A study of Mus musculus with 48 samples.

How the data were processed

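RNA was measured in 48 libraries from NIH 3T3 mouse fibroblasts, an immortalised embryonic cell line with a circadian clock of its own. Per the labels, 2 stable lines were compared, one with a control hairpin (shCTRL) and one with a hairpin against Bmal1 (shBmal1; the files call this gene Arntl). Both lines were synchronised with 50% horse serum for 2 h and collected every 2 h from 24 to 46 h, so that each line had 12 time points. From each culture 2 libraries were made, one of total RNA and one of newly made RNA that had taken up the uridine analogue 4sU and was recovered by biotin and streptavidin. This gave 4 groups of 12 libraries and 1 library per group and time point. Per the labels' protocols, 30 ug of RNA entered each pull-down, about 50% of the RNA in shCTRL and 60 to 70% in shBmal1, the remainder served as total RNA, and sequencing was paired-end, strand-specific and depleted of ribosomal RNA. Yeast RNA and a labelled DNA/RNA hybrid were added before the pull-down per the labels' protocols; the deposited tables hold no values for these spike-ins, which were not analysed here.

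The authors deposited 2 tables, one for exons and one for introns, each with RPKM (reads per kilobase of feature, scaled to the library's total of mapped reads) for 11313 gene symbols in the 48 libraries. Per the submitters' processing notes, reads were trimmed with Trim Galore and handled with HOMER 4.11.1 on mm10 (GRCm38.p6); the aligner is not given in the sources used here. The reference annotation of GRCm38.p6 held 10747 (95.0%) of the symbols and supplied the coordinates. Total exon RPKM served as the measure of RNA level, 4sU intron RPKM as the measure of RNA synthesis, and the log2 difference of 4sU exon minus total exon of the same culture (the 4sU/total ratio) as the measure of newly made RNA relative to the RNA present. The 4sU exon and total intron values were analysed by the same model outside these comparisons.

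Depth was recovered from the deposited RPKM, because the values of lowly expressed genes were whole multiples of what 1 read is worth. Exon totals came out as whole numbers of reads, 48873013 to 76260143 per library. The mean was 64862581 ± 6607250 reads (SD, n = 12) in shCTRL total RNA, 60250291 ± 6266226 in shBmal1 total RNA, 63030517 ± 6503820 in shCTRL 4sU and 57539152 ± 5284154 in shBmal1 4sU. The same step gave the transcript length behind each gene's RPKM, with lengths taken as equal within 0.1%. On simulated exon tables the step returned 48 of 48 totals and 99.9% of the lengths, while intron totals and intron lengths were not simulated. Intron totals were found relative to 1 shCTRL total RNA library, whose intron total was taken as its exon total. They lay within 0.0623 of whole numbers. On that basis they equalled the exon totals in 36 libraries and were 1.35 to 1.39 times larger in the 12 shBmal1 4sU libraries. Deposited intron RPKM was therefore not on 1 scale across the groups.

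For the comparisons, the RPKM of each layer were scaled by the median ratio of each library to the geometric mean library of its layer, and put on a log2 scale with a pseudocount of 0.1 for exons and 0.02 for introns. A fold change is therefore on the log2(scaled RPKM + pseudocount) scale, which understates changes of low genes. Genes with a mean of at least 0.5 exon RPKM or 0.1 intron RPKM were tested: 10912 in total exon, 10509 in 4sU intron and 10870 in the ratio. Each layer was fitted with limma 3.58.1 in R 4.3.3 (empirical Bayes with trend and robust variance) on its 24 libraries, with a mean per line and cosine and sine terms of 24-h and 12-h period per line. The shBmal1 minus shCTRL mean was called at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. Rhythms of each line and period, and their difference between the lines (differential rhythm), were called at an adjusted p under 0.05 by moderated F tests. P-values were adjusted by the Benjamini-Hochberg method within each layer and test. Amplitude is the fitted distance from mean to peak on the log2 scale, and peak is in h after serum. Every p-value measures the spread between single libraries around the fitted curves, since no time point had a second library in its group, and 1 stable line of each kind was studied, so the spread between independent lines is unknown.

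The 25 gene lists (the core clock, clock outputs, cell cycle, stress, metabolism, matrix, RNA decay and transcription groups, and markers of other cell types) were written before the data were examined, as were the tests, the thresholds, the rule for naming genes and the other settings to be tried, apart from those named as later additions. Lists were tested with camera in limma at a preset correlation of 0.01, again with an estimated correlation, and with fry, which tests whether a list's genes move on balance in one direction. List members are counted as higher or lower at an adjusted p under 0.05 with no size threshold. Many of all tested genes pass that rule, so their counts are given beside those of the lists. Rhythmic list members were counted against all tested genes by Fisher's exact test, one-sided for more members than expected. That test takes genes as independent, so its p-values are too small wherever the members of a list vary together between libraries. The genes named are all measured core clock members and those of the rules that follow. For line means, they are the 6 highest and 6 lowest log2 fold changes of total exon and of 4sU intron and the 4 and 4 of the ratio among called genes changed the same way at all 12 time points with at least 1 RPKM (exon) or 0.2 RPKM (intron) in the higher line. For rhythms, they are the 6 largest amplitudes among called genes per line and period (4 for the ratio) with the same minimum. For differential rhythm, they are the 6 smallest p per layer and period, and for each list described up to 4 members with the smallest p. Some genes that the rule names are not given in the text. Unnamed gene models and small RNAs were left out of the line mean, rhythm and differential rhythm parts of the rule. Genes with 1 transcript length in both lines were named separately by the line mean rule, a choice made after the values were seen.

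The model was tested on simulated data. In total exon it called 89.4% of 24-h rhythms with an amplitude of 0.5 and 64.2% of those with 0.25, and 89.6% and 49.3% of 12-h rhythms. In 4sU intron it called 91.0% and 35.8% of 24-h rhythms, and 85.1% and 44.8% of 12-h rhythms, of those amplitudes. In the ratio it called 73.1% and 29.9% of 24-h rhythms. Line means with a true log2 fold change of 1.5 were called in 100% of cases in total exon, and those of exactly 1, on the size threshold, in 49.3%. The simulated noise was independent between genes and had 1 spread for both lines, and rhythms were put into shCTRL alone. In the real total exon values the median residual variance of shBmal1 was 1.79 times that of shCTRL. The rates therefore do not carry over to shBmal1 or to noise that genes share. Other settings tried were as-deposited RPKM, a pseudocount 10 times larger, no filter on low values, no size threshold, a time point block, no time terms, a linear trend over time, an adjusted p under 0.2, separate fits of the lines, 4sU exon as the measure of synthesis for the peak lag, and leaving out each time point. Added after the data were seen were genes of 1 length only, leaving out the shCTRL 30 h culture, removing a trend on length, removing a component that sets the 30 h culture apart, and voom weights on the recovered reads. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.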

Results

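RNA levels and newly made RNA were followed through a day after serum in control fibroblasts and in fibroblasts with a hairpin against Bmal1, the gene of a core activator of the circadian clock. Each of the 4 groups (shCTRL total, shBmal1 total, shCTRL 4sU and shBmal1 4sU) had 12 libraries, 1 at each time point from 24 to 46 h after serum. Depth was 53931845 to 76260143 reads in shCTRL total RNA and 50977879 to 69829031 in shBmal1 total RNA. In the 4sU libraries it was 48873013 to 71451107 in shCTRL and 51841130 to 67576474 in shBmal1. The listed genes took a mean of 68.1% and 69.4% of the exon total in the shCTRL and shBmal1 total libraries, and 59.2% and 61.2% in the 4sU libraries. Errors below are standard errors of the limma fit unless an SD is named, and a log2 fold change is shBmal1 minus shCTRL over the 12 time points of each line.

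Arntl, the targeted gene, lay on chromosome 7 from 113178471 to 113314126 (GRCm38.p6). Its total exon level averaged 9.25 ± 6.03 RPKM (SD, n = 12) in shCTRL and 3.74 ± 0.726 RPKM in shBmal1. The log2 fold change was -0.92 ± 0.0811 (limma adjusted p = 3.70e-09). In shCTRL the log2 level rose from 0.52 at 24 h through 1.24, 2.27, 3.20 and 4.00 to 4.13 at 34 h. It then went through 4.01, 3.92, 3.76, 3.08 and 2.11 to 1.76 at 46 h. In shBmal1 it was 1.23 at 24 h and then 1.77, 1.47, 1.82, 2.15, 2.27, 2.14, 1.99, 2.11, 2.05, 1.89 and 2.09. The shBmal1 libraries were thus lower at 9 of 12 time points and higher at 24, 26 and 46 h, when shCTRL was near its trough. Newly made Arntl intron RNA was 0.635 ± 0.352 RPKM (SD) in shCTRL and 0.831 ± 0.185 in shBmal1, a log2 fold change of 0.57 ± 0.0810 (limma adjusted p = 1.51e-05), higher at 8 of 12 time points. It was lower in shBmal1 at 32, 34, 36 and 38 h, around the shCTRL peak (log2 level 0.02 against 0.18 at 34 h). Without time terms in the model the intron difference was still 0.57 but did not pass the test (adjusted p = 0.0848, range over the alternatives 8.38e-06 to 0.187). On the RPKM as deposited it was 0.11, where the median of all genes was -0.45.

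The first comparison asked which RNAs differed in level between the lines over the whole course. Aldh3a1, an aldehyde dehydrogenase, fell from 76.2 ± 14.5 to 15.9 ± 3.40 RPKM (SD, n = 12 per line), a log2 fold change of -2.26 ± 0.0813 (limma adjusted p = 3.30e-15). Tmsb4x, which encodes the actin-binding thymosin beta 4, fell from 87.4 ± 3.62 to 20.8 ± 2.00 RPKM, a change of -2.07 ± 0.0481 (2.86e-18). Plet1, Mymx (a membrane protein of myoblast fusion) and Aspn (asporin, a small matrix proteoglycan) changed by -2.23 ± 0.134, -2.23 ± 0.125 and -2.13 ± 0.132. The proliferin genes Prl2c3 and Prl2c2 were higher by 3.21 ± 0.159 and 2.84 ± 0.126, and Mttp, a lipid transfer protein, by 2.15 ± 0.256. Prl2c2 and Prl2c3 are near-identical paralogs, so the share of each is uncertain. Atp5md (3.39 ± 0.055), Bcat1 (2.46 ± 0.0389), Dnajc19 (2.12 ± 0.0455) and Oplah (-2.06 ± 0.0793) also led the fold changes. Each of these 4 carried a different transcript length in the RPKM of the lines. All genes of this paragraph had their direction at 12 of 12 time points. Of 10912 genes tested with limma, 97 were higher and 148 lower in shBmal1. Among the 245, 63 (25.7%) had 2 lengths, against 584 (5.35%) of all genes tested (one-sided Fisher's exact test across genes, p = 1.07e-26). Genes with 1 length made up 60 of the higher and 121 of the lower. Named from the genes with 1 length, after their values were seen, were the connexin gene Gjb5 (1.90), Gna15 (1.78) and Plet1os (-2.04).

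Several gene groups moved together in total RNA. Members are counted with no size threshold, and by that rule 3748 of all 10912 genes were higher in shBmal1 and 3619 lower. Of 24 measured G1/S genes, 21 were higher in shBmal1 and 0 lower (21 adjusted over the list alone). Among them were the replication genes Mcm2 (0.58 ± 0.0486), Mcm3 (0.60 ± 0.0548) and Cdt1 (0.55 ± 0.0465) and the transcription factor E2f2 (1.26 ± 0.075). Of 24 G2/M genes, 14 were higher and 1 lower, with Cdk1 at 0.76 ± 0.0634 and Aurka at 0.84 ± 0.0813. Of 17 p53 targets, 13 were higher and 2 lower (13 and 3 adjusted over the list alone). The p53 antagonist Mdm2 was at 0.88 ± 0.0645 and the stress gene Sesn2 at 1.09 ± 0.0619. Ribosomal protein genes (24 higher and 1 lower of 26; Rps3 0.49, Rpl27 0.75) and oxidative phosphorylation genes (16 and 1 of 22; Cox7a2 0.45, Ndufa4 -1.10) also moved upward. So did actin and SRF targets (8 and 1 of 14; Acta2 0.53, Tpm1 0.45) and glycolysis genes (12 and 4 of 19; Pgk1 and Ldha 0.76 each). The camera adjusted p over 20 lists was 6.50e-05 for G1/S, 6.81e-05 for ribosomal proteins and 0.000166 for oxidative phosphorylation. It was 0.00109 for p53 targets, 0.0332 for G2/M and for actin, and 0.0429 for glycolysis. None of these camera calls held with an estimated correlation: the adjusted p was 0.290, 0.279, 0.290, 0.143, 0.677, 0.290 and 0.279 in that order. By fry all of these lists passed, with adjusted p from 4.39e-11 for p53 targets to 0.00353 for G2/M. Fry does not weigh a list against all other genes. In total exon every list tested passed it but clock outputs (fry adjusted p = 0.329) and cholesterol synthesis (0.310).

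Other groups held members that went both ways, as all genes did by the same rule (3748 higher and 3619 lower of 10912). Extracellular matrix genes were lower in 15 and higher in 8 of 24 (camera adjusted p = 0.0559, 0.677 with an estimated correlation, and fry adjusted p = 1.99e-05). Bgn, a matrix proteoglycan, was at -0.81 ± 0.0452 (605 ± 41.5 against 347 ± 27.5 RPKM, SD) from shCTRL to shBmal1, the collagen Col3a1 at -0.90 ± 0.0525 and Thbs1 at -0.88 ± 0.0574. Inflammatory and NF-kB genes were lower in 9 and higher in 4 of 18 (camera adjusted p = 0.238), with the complement gene C3 at -1.23 and Ptgs2, the inducible cyclooxygenase, at 1.70 ± 0.0743. Immediate early genes were higher in 10 and lower in 6 of 20 (0.238; Btg2 1.45 ± 0.0649). NRF2 targets were higher in 11 and lower in 4 of 21 (11 and 7 adjusted over the list alone; 0.238; Hmox1 0.78 ± 0.0483, Fth1 -0.75). The unfolded protein response split into 9 higher and 10 lower of 24 (0.761; Edem1 -0.74) and mRNA decay factors into 11 and 14 of 39 (0.354; Ago2 -0.77 ± 0.0281), and both list medians went from -0.04 to 0.04 on the RPKM as deposited, with that of all genes going from 0.01 to 0.09. Transcription and splicing genes split into 13 and 7 of 29 (0.395; Med1 -0.51), heat shock genes into 4 and 3 of 13 (0.678; Hspe1 0.51) and interferon genes into 1 and 3 of 7 (0.292; Gbp2 -1.38). Cholesterol synthesis genes split into 7 and 5 of 22 (5 and 5 adjusted over the list alone; 0.810; Cyp51 -0.33). Among markers of other cell types, the keratin Krt14 was higher by 1.61 ± 0.0738. Of 4 leukocyte markers Lyz2 was higher (0.84 ± 0.0685), while Cd68 was at 0.25 with an adjusted p of 0.0773. Plin4 (-0.45), 1 of 2 adipocyte markers, was lower. The 1 measured neural marker was lower, with a log2 fold change of -1.36. No endothelial marker passed the filter on low values, and 1 replication-dependent histone did (H2bc4, 0.07, adjusted p = 0.380).

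Clock genes formed the group closest to the targeted protein. Of 16 measured core clock genes, 9 were lower in shBmal1 and 3 higher (camera adjusted p = 0.0606, 0.279 with an estimated correlation, and fry adjusted p = 1.07e-10). By the same rule 3619 of all 10912 genes were lower and 3748 higher. Nr1d1, a repressor whose gene the Bmal1 protein activates, fell from 72.0 ± 51.6 to 19.4 ± 5.66 RPKM (SD), a change of -1.56 ± 0.0552 (limma adjusted p = 2.56e-15) seen at 12 of 12 time points. Nr1d2 changed by -1.68 ± 0.072, Per3 by -1.29 ± 0.0608, Rora by -1.19 ± 0.0955, Clock by -0.36 ± 0.0811, Bhlhe40 by -0.24 ± 0.0378 and Csnk1d by -0.12. Cry1, Cry2 and Per2, the genes of clock repressors, were higher by 0.67 ± 0.0454, 0.43 ± 0.0573 and 0.17 ± 0.048. Per1 (0.11), Ciart (-0.18), Bhlhe41 (-0.10) and Csnk1e (0.06) did not pass the test, with adjusted p of 0.0647, 0.343, 0.105 and 0.0784. Of 18 clock output genes, 6 were higher and 4 lower (camera adjusted p = 0.810), among them the transcription factors Dbp (-1.31 ± 0.0837), Tef (-0.79 ± 0.0629), Nfil3 (1.23 ± 0.0961) and Klf10 (0.27 ± 0.0314).

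The second comparison asked where the newly made intron RNA, as a measure of synthesis, differed between the lines. Among genes with 1 length, named after their values were seen, Prl2c2 was higher in shBmal1 by 2.22 ± 0.131, Atg9b by 1.68 ± 0.112 and Ptgs2 by 1.46 ± 0.0753. By the same choice Plet1os (-1.97 ± 0.102), Aldh3a1 (-1.85 ± 0.101) and the growth factor gene Igf2 (-1.46 ± 0.0909) were lower. In the clock, Nr1d2 (-1.51 ± 0.0672), Per3 (-1.05 ± 0.0458), Rora (-0.85 ± 0.0818) and Nr1d1 (-0.65 ± 0.0633) were lower and Cry1 (0.86 ± 0.0622) was higher, as in total RNA. Dbp changed by -0.88 ± 0.0957 and Nfil3 by 1.02 ± 0.119. Of the 16 core clock genes 4 were higher and 6 lower (4 and 7 adjusted over the list alone, camera adjusted p = 0.324, fry adjusted p = 1.82e-07). By the same rule 2361 of all 10509 genes were higher and 2307 lower. The differences of Clock (0.17) and Cry2 (0.31) were -0.29 and -0.15 on the RPKM as deposited, where the median of all genes was -0.45. The genes with the most extreme values all had 2 intron lengths. Those higher were Phactr1 (6.68 ± 0.0424), Rad54l2 (4.34), Has2os (3.88), Evi5l (3.09), Oxr1 (2.74) and Ccdc163 (2.53), and those lower Ccnd3 (-4.09 ± 0.0763), Ermp1 (-3.31), Nr2c2 (-3.27), Ago3 (-2.44), Daxx (-2.26) and Kmt2e (-2.19).

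Of 10509 genes tested with limma in 4sU intron RNA, 55 were higher and 38 lower. Of these 93, 44 (47.3%) had 2 lengths, against 431 (4.10%) of all genes tested (one-sided Fisher's exact test, p = 1.23e-36). On the RPKM as deposited the split was 27 higher and 229 lower, since the median of all genes moved from 0.01 to -0.45. That shift covers all genes alike, and with it the sign of each group median that follows turned, except in the extracellular matrix. Group members are counted with no size threshold, by which 2361 of the 10509 genes were higher and 2307 lower. G2/M genes were higher in 19 and lower in 0 of 24 (median 0.42, as deposited -0.04; Cdk1 0.52 ± 0.0801, Bub1b 0.56 ± 0.0813). P53 targets were higher in 14 and lower in 1 of 17 (0.46 and -0.02; Mdm2 1.16 ± 0.0868, Sesn2 0.90), and G1/S genes were higher in 16 and lower in 0 of 24 (0.30 and -0.14; Mcm3 0.69 ± 0.0711). Ribosomal protein genes were higher in 15 of 26 (17 adjusted over the list alone; 0.21 and -0.27; Rps3 0.55). So were actin and SRF targets in 8 of 12 (0.23 and -0.21; Actb 0.62) and oxidative phosphorylation genes in 7 of 22, with 1 lower (0.11 and -0.36; Cox6c 0.62). Extracellular matrix genes were lower in 14 and higher in 4 of 24 (15 lower adjusted over the list alone; median -0.20, as deposited -0.67; Col3a1 -0.82 ± 0.0693, Dcn -0.98 ± 0.0986). The camera adjusted p was 1.17e-05 for G2/M and for p53, 6.67e-05 for G1/S, 0.000352 for ribosomal proteins, 0.00433 for matrix, 0.0108 for actin and 0.0431 for oxidative phosphorylation. None held with an estimated correlation, where the adjusted p was 0.10 for p53 targets, 0.412 for ribosomal proteins and 0.410 for the others. All of them passed by fry, with adjusted p from 3.27e-08 for p53 targets to 0.00179 for ribosomal proteins.

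The third comparison asked where the 4sU/total ratio, newly made RNA relative to the RNA present, differed between the lines. The clock genes Nr1d1 (0.29 ± 0.0381, limma adjusted p = 2.58e-05) and Arntl (0.20 ± 0.0412, 0.00167) had a higher ratio in shBmal1. So had Bhlhe40 (0.19), Csnk1d (0.16), Per1 (0.14), Cry1 (0.16), Per3 (0.17) and Rora (0.15), while Csnk1e (-0.11) had a lower one, 8 and 1 of 16 in all. By the same rule, with no size threshold, 1765 of all 10870 genes had a higher ratio and 1290 a lower one. In the extracellular matrix the ratio was higher in 10 and lower in 1 of 24 genes (10 and 2 adjusted over the list alone), with Thbs1 at 0.29 ± 0.0349 and Fbn1 at 0.27 ± 0.0362. Ribosomal protein genes were lower in 10 and higher in 3 of 26 (18 and 3 adjusted over the list alone; Rps9 -0.35), and oxidative phosphorylation genes lower in 12 and higher in 2 of 22 (14 and 2 adjusted over the list alone; Cox4i1 -0.34, Ndufa4 0.33). The camera adjusted p was 0.00280, 0.00845, 0.010 and 0.0471 for ribosomal proteins, oxidative phosphorylation, core clock and matrix, and none held with an estimated correlation (adjusted p of 0.231, 0.231, 0.198 and 0.545). The fry adjusted p was 0.000442, 0.0447, 1.21e-06 and 0.000442 in that order. With the size threshold, limma called 33 genes higher and 33 lower of 10870. They were led by Pcf11 (3.56), Mrpl42 (2.26), Smarcb1 (2.20) and Wdr27 (2.06) and by Atp5md (-3.05), Dnajc19 (-2.06), Eif4e2 (-1.76) and Ypel1 (-1.67). All 8 of these had more than 1 length, as had 64 of the 66 (97.0%). Among genes with 1 length limma thus called 0 higher and 2 lower, with 2434 higher and 1854 lower at an unadjusted p under 0.05 among all genes.

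**Figure D1:**
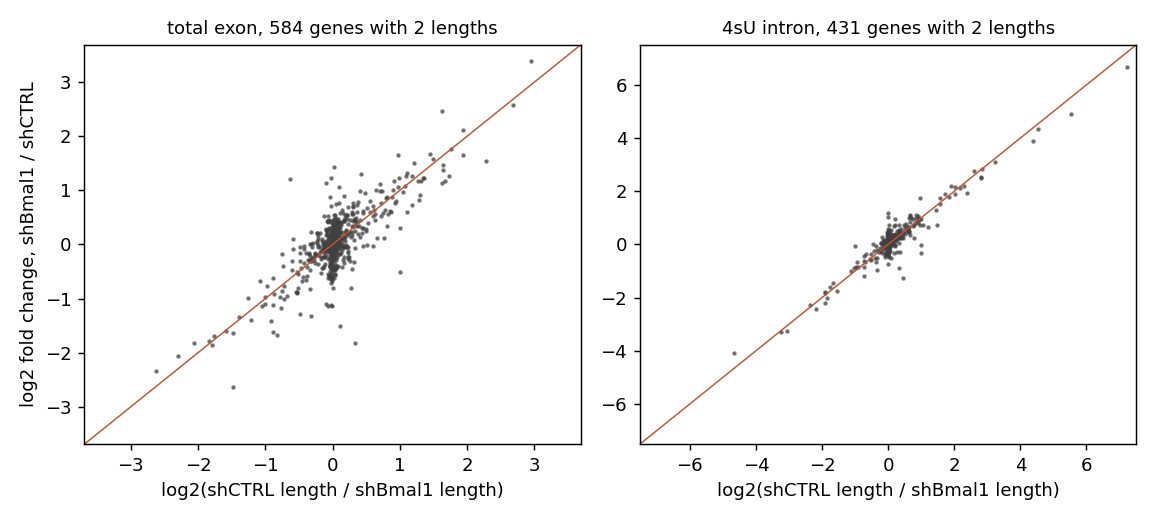
The log2 fold change (shBmal1 minus shCTRL) is plotted against the log2 ratio of the transcript length behind the shCTRL RPKM to that behind the shBmal1 RPKM, 1 point per gene whose lengths differ, for 584 genes of total exon and 431 of 4sU intron, with the line of identity. Points follow the line, with a correlation across genes of 0.811 and 0.949.

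The next comparison asked which RNAs of shCTRL had a 24-h rhythm. Clock genes and their outputs led. The amplitude of Dbp was 1.63 ± 0.0837 with a peak at 47.4 h, that of Arntl 1.59 ± 0.0811 at 35.9 h, and that of Nr1d1 1.51 ± 0.0552 at 44.2 h. Their peak-to-trough folds were 9.56, 9.10 and 8.11. Per2 (1.36 ± 0.048) peaked at 25.7 h, Nfil3 (1.25 ± 0.0961) at 34.5 h and Tef (1.24 ± 0.0629) at 24.0 h. Limma called 11 of 16 core clock genes (12 adjusted over the list alone) and 7 of 18 clock outputs (9 adjusted over the list alone), against 396 (3.63%) of 10912 genes. Extracellular matrix genes were called in 13 of 24 (21 adjusted over the list alone), such as Lox (0.55 ± 0.0643, 40.5 h) and Fbn1 (0.48 ± 0.0454, 39.2 h). G2/M genes were called in 6 of 24 (13 adjusted over the list alone), with peaks from 29.5 to 30.6 h (Cdk1 0.37 ± 0.0634, Kif20a 0.40, Ccnb1 0.36). Inflammatory genes were called in 5 of 18 (7 adjusted over the list alone), and of the 4 leukocyte markers Lyz2 (0.35) and Cd14 (0.24) were called (2 adjusted over the list alone). Fisher's exact test, one-sided and adjusted over the lists, gave 4.65e-12 for core clock and for matrix, 1.18e-05 for outputs, 0.000849 for G2/M, 0.00142 for inflammatory genes and 0.0250 for the leukocyte markers. With a linear term for time limma called 112 genes, with 11 core clock genes, 5 matrix genes and 0 G2/M genes. The count of 396 was 204 without the 38 h or the 40 h time point, 242 without 42 h and 262 without 44 h, and up to 467 without another.

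Newly made intron RNA of shCTRL had 116 genes (1.10% of 10509) with a 24-h rhythm by limma. Dbp (1.45 ± 0.0957, 46.4 h), Per2 (1.22 ± 0.0547, 24.7 h), Arntl (1.18 ± 0.081, 34.6 h), Tef (1.16 ± 0.0581, 47.3 h), Nfil3 (1.12 ± 0.119, 34.1 h) and Nr1d2 (1.06 ± 0.0672, 45.5 h) had the largest amplitudes. They included 9 of 16 core clock genes (9 adjusted over the list alone; Fisher adjusted p = 3.62e-13), 5 of 17 outputs (9 adjusted over the list alone; 5.30e-06) and 6 of 24 matrix genes (15 adjusted over the list alone; 1.73e-06). G2/M genes were called in 2 of 24 (21 adjusted over the list alone; 0.108) and NRF2 targets in 2 of 20 (4 adjusted over the list alone; 0.0958). Of the genes tested in both layers, 362 were rhythmic in total exon and 116 in 4sU intron, and 86 in both, against 4.07 by chance. The count of 116 was 45 with a linear term and 47, 49, 61, 61, 63, 70, 75, 77, 184 and 207 without the 38, 40, 36, 42, 44, 34, 26, 30, 46 and 24 h time point.

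In shBmal1, limma called rhythms of clock, cell cycle, inflammatory and matrix genes. Arntl had an amplitude of 0.30 ± 0.0811 (limma adjusted p = 0.0487), Dbp 0.47 ± 0.0837, Per2 0.38 ± 0.048 and Nr1d1 0.55 ± 0.0552, and 7 of 16 core clock genes were called (9 adjusted over the list alone). G2/M genes were called in 20 of 24 (24 adjusted over the list alone), with peaks from 28.7 to 30.0 h (Ccnb1 0.51 ± 0.0752, Cdk1 0.44 ± 0.0634). G1/S genes were called in 17 of 24 (19 adjusted over the list alone), with peaks from 27.6 to 29.8 h (Rrm2 0.51 ± 0.0637, Mcm7 0.41 ± 0.0497). Inflammatory genes were called in 12 of 18 (12 adjusted over the list alone), with peaks from 40.2 to 42.2 h (C3 0.74 ± 0.0906), and matrix genes in 16 of 24 (20 adjusted over the list alone; Col5a2 0.40 ± 0.0412, 40.5 h). NRF2 targets were called in 10 of 21 (14), cholesterol genes in 9 of 22 (10) and glycolysis genes in 7 of 19 (10), with the count over the list alone in brackets. The largest amplitudes were those of Mttp (1.31 ± 0.256, 36.4 h), Prl2c3 (1.06, 29.3 h), the chemokine Ccl5 (0.97, 40.4 h), Prl2c2 (0.94, 29.1 h), the acute-phase gene Saa3 (0.87, 40.8 h) and the matrix gene Ogn (0.84, 40.7 h). The adjusted p of Fisher's test was 1.20e-14 for G2/M, 1.03e-10 for G1/S, 1.18e-09 for matrix and 1.85e-07 for inflammatory genes. It was 0.000135 for NRF2 targets, 0.00117 for cholesterol synthesis, 0.00289 for the core clock and 0.00822 for glycolysis. The estimated correlation between members was 0.563 in G2/M, 0.334 in G1/S, 0.348 in matrix and 0.402 in inflammatory genes. Fisher's test takes genes as independent, so its p-values are too small for these lists.

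Of 10912 genes, limma called 1225 (11.2%) with a 24-h rhythm in shBmal1, and 170 genes were called in both lines, against 44.5 by chance. The order of the lines turned when each line was fitted alone, with 325 genes in shBmal1 and 707 in shCTRL, and with a linear term the counts were 13 and 112. The 1225 calls became 381 without the 40 h time point, 724 without 38 h, 775 without 42 h and 779 without 30 h, and up to 1828 without another. With the linear term 0 members of the G2/M, G1/S, matrix, inflammatory, NRF2, cholesterol and glycolysis lists were called in shBmal1 by limma, and 1 core clock gene was. The mean log2 level of G2/M genes went from 0.51 above their line mean at 24 h to -0.52 at 46 h in shBmal1 and from 0.26 to -0.39 in shCTRL, and that of inflammatory genes from -0.38 to 0.45 in shBmal1.

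**Figure D2:**
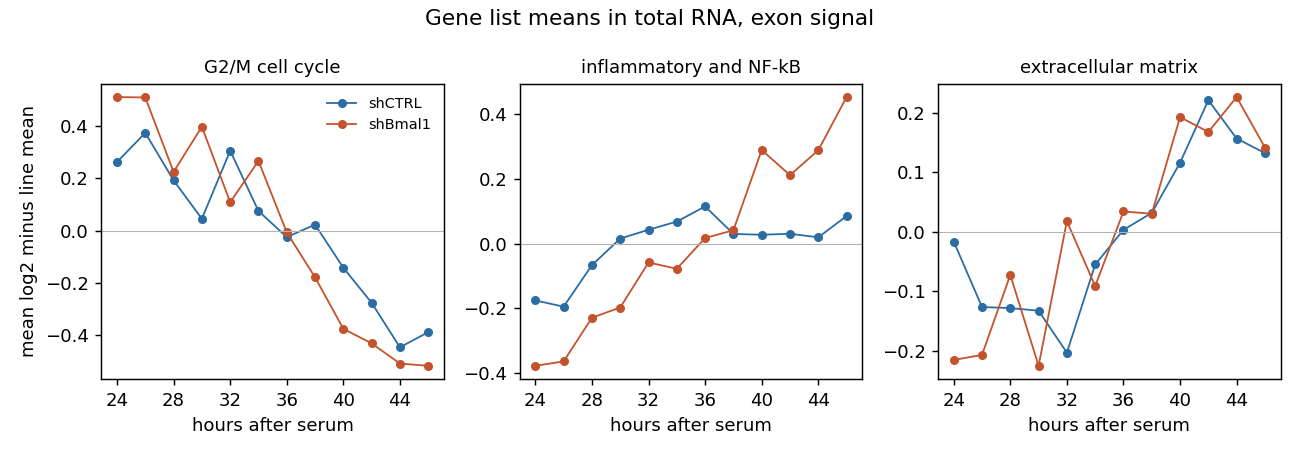
Mean log2 level minus its line mean is plotted against hours after serum for the G2/M, inflammatory and NF-kB, and extracellular matrix lists in total exon RNA, 1 library per point, shCTRL in blue and shBmal1 in orange. G2/M genes in shBmal1 go from 0.51 at 24 h to -0.52 at 46 h, and inflammatory genes from -0.38 to 0.45.

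Newly made intron RNA of shBmal1 had 634 genes (6.03%) with a 24-h rhythm by limma. Prl2c2 (1.07 ± 0.131, 29.3 h), Samd1 (0.86 ± 0.187, 43.2 h), the transcriptional regulator Cited2 (0.85 ± 0.182, 42.2 h), B3gnt9 (0.82, 41.9 h) and Atf5 (0.77, 42.5 h) were among those with the largest amplitudes. G2/M genes were called in 18 of 24 (24 adjusted over the list alone; Fisher adjusted p = 1.62e-16), G1/S genes in 7 of 24 (13 adjusted over the list alone; 0.00375) and core clock genes in 4 of 16 (9 adjusted over the list alone; 0.0362). Clock outputs (5 of 17, Wee1 0.50), cholesterol genes (6 of 22, Cyp51 0.25), inflammatory genes (5 of 17, Saa3 0.68) and matrix genes (6 of 24, Thbs2 0.36) had a Fisher adjusted p of 0.00839 each. Their counts adjusted over the list alone were 8, 9, 7 and 12. Ribosomal protein genes were called in 5 of 26 (18 adjusted over the list alone; 0.0427; Rps14 0.57). When each line was fitted alone the call counts were 26 in shBmal1 and 269 in shCTRL, and with a linear term 6 and 45, so the order of the lines turned here too. With the linear term limma called 0 G2/M, G1/S, cholesterol, inflammatory and matrix genes in shBmal1, 1 clock output and 3 core clock genes. The 634 calls became 139, 238, 304, 310, 339, 415 and 1545 without the 40, 30, 42, 34, 36, 38 and 32 h time point.

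The central comparison asked which rhythms themselves differed between the lines. Per2 led in total RNA: its fitted 24-h curves differed by 1.03 on the log2 scale (limma adjusted p = 7.45e-08), with an amplitude of 1.36 in shCTRL and 0.38 in shBmal1. The difference was 0.93 for Cry1 (amplitudes 1.15 and 0.23), 0.98 for Nr1d1 (1.51 and 0.55), 1.32 for Arntl (1.59 and 0.30), 0.58 for Bhlhe40 (0.60 and 0.03) and 1.36 for Nfil3 (1.25 and 0.13), with adjusted p from 8.10e-08 to 2.17e-05. The adhesion gene Vcam1 had like amplitudes of 0.42 and 0.43 but peaked at 29.2 h in shCTRL and at 40.9 h in shBmal1 (difference 0.85, adjusted p = 0.000574). A straight fall over these time points has a fitted peak at 29.0 h and a straight rise at 41.0 h. By contrast the differences of Cdk1 (0.10), Ccnb1 (0.16), Kif20a (0.13) and Rrm2 (0.26) did not pass, with adjusted p of 0.855, 0.760, 0.855 and 0.362, so these rhythms were not shown to differ between the lines.

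In all, limma called 93 genes with a differential 24-h rhythm in total exon RNA, 66 with the larger amplitude in shCTRL and 27 in shBmal1, among them 9 of 16 core clock genes (10 adjusted over the list alone). The amplitude was smaller in shBmal1 in 12 of the 16, with medians of 0.69 and 0.20. In 4sU intron RNA 31 genes were called, 19 with the larger amplitude in shCTRL and 12 in shBmal1, and 7 core clock genes (9 adjusted over the list alone). Spon2, a secreted matrix protein (0.80), Per2 (0.75) and Tef (0.78) led with an adjusted p of 2.81e-04 each, followed by Arntl (1.05, 0.000357), Cry1 (0.78) and the protease Prss23 (0.72). The layers shared 17 of these genes, among them Arntl, Bhlhe40, Cry1, Dbp, Nfil3, Nr1d2, Per1, Per2, Per3 and Tef. With a linear term 30 and 10 genes were called. The 93 became 39 without 38 h or 40 h, 45 without 36 h, 51 without 44 h, 55 without 42 h, 60 without 30 h and 173 without 32 h. The 31 became 8, 10, 11, 12, 13, 14, 20, 52 and 245 without 44, 36, 34, 42, 30, 40, 38, 26 and 32 h.

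**Figure D3:**
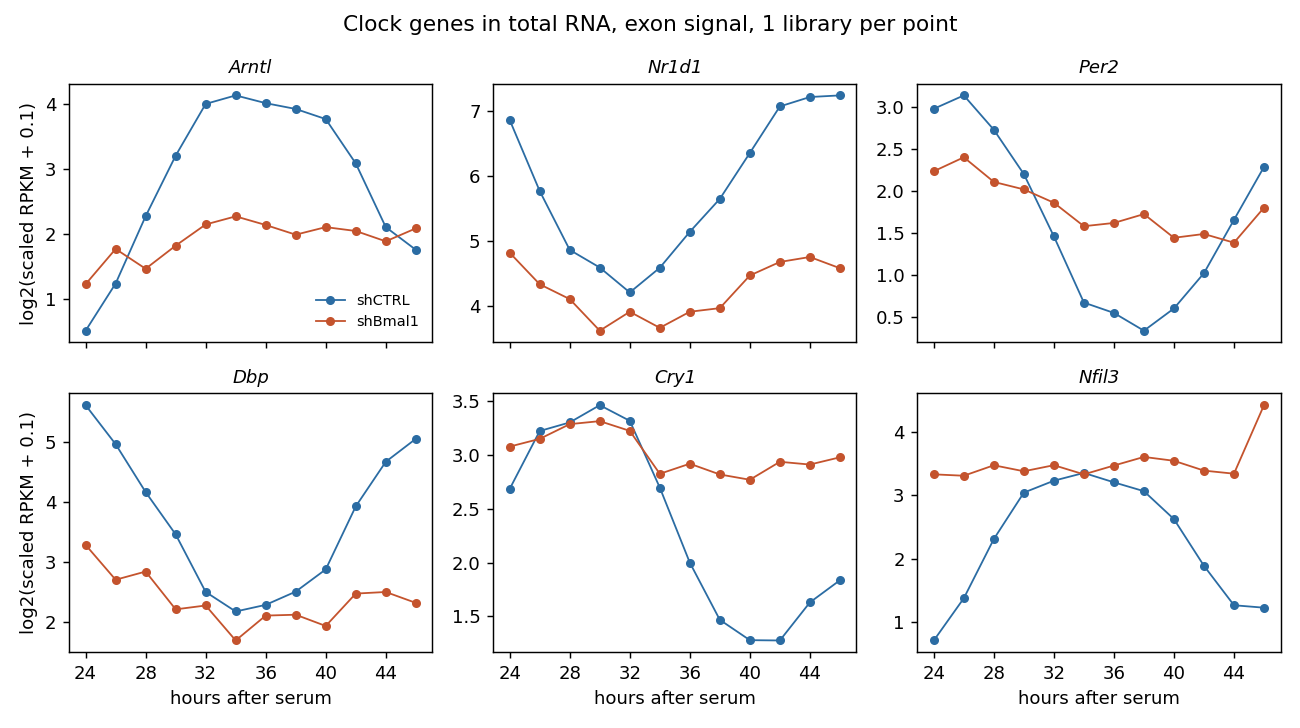
The log2 of scaled total exon RPKM + 0.1 is plotted against hours after serum for Arntl, Nr1d1, Per2, Dbp, Cry1 and Nfil3, 1 library per point, shCTRL in blue and shBmal1 in orange. Arntl goes from 0.52 to 4.13 in shCTRL and stays between 1.23 and 2.27 in shBmal1.

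The title of the series names 12-h RNA patterns, so rhythms of that period were asked for in each line. In total exon RNA of shBmal1, Cdt1, a replication licensing factor, had a 12-h amplitude of 0.32 ± 0.0465 with a peak at 25.8 h, and Pdzd2 one of 0.24 ± 0.0341 with a peak at 32.1 h, both with a limma adjusted p of 0.0328. These were the 2 genes called in shBmal1, where 2650 had an unadjusted p under 0.05. The count of 2 was 154 on the RPKM as deposited, 0 with a linear term, 1980, 1301, 472 and 167 without the 32, 26, 24 and 30 h time point, and 0 without any other. In shCTRL limma called 0 genes (353 at an unadjusted p under 0.05), or 2 without 46 h. In 4sU intron RNA limma called 0 in shCTRL (294 unadjusted) and 0 in shBmal1 (2050 unadjusted; 709 called without 32 h and 169 without 24 h), and in the ratio 0 and 0 (468 and 511 unadjusted). G1/S genes held 1 called member, or 14 of 24 adjusted over the list alone (Fisher adjusted p = 0.0879). In total exon RNA of shBmal1 limma called 0 members of the next lists over all genes. Adjusted over the list alone, it called 9 of 24 matrix, 9 of 22 oxidative phosphorylation, 8 of 24 G2/M, 7 of 18 inflammatory, 6 of 19 glycolysis and 6 of 17 p53 genes. In 4sU intron RNA the counts adjusted over the list alone were 14 of 24 for G2/M, 9 of 24 for G1/S, 9 of 26 for ribosomal proteins and 5 of 16 for the core clock. For 12-h rhythms that differ between the lines limma called 0 genes in total exon, 4sU intron and ratio (508, 415 and 446 at an unadjusted p under 0.05). In total intron RNA, a second measure, it called 2 of 10019 (959 unadjusted), Acp4 and Dna2 (curves apart by 0.58 and 0.44, adjusted p = 0.0339 and 0.0372). In that layer 54 genes had a 12-h rhythm in shBmal1 by limma. Neither random orders nor left-out time points were tried on total intron RNA, so how stable these calls are was not tested. The smallest p were those of Prmt5 and Tlr2 in total exon (curves apart by 0.22 and 0.29, adjusted p = 0.954 each) and of Mad2l2 and Hirip3 in 4sU intron (0.46 and 0.45, adjusted p = 0.949 each).

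Whether RNA levels followed synthesis was asked in the 86 genes rhythmic in both layers of shCTRL. Arntl peaked at 34.6 h in 4sU intron RNA and at 35.9 h in total exon RNA, Dbp at 46.4 and 47.4 h, and Per2 at 24.7 and 25.7 h. The circular median lag was 1.05 h (quartiles 0.463 to 1.73 h), with total exon later in 73 genes and earlier in 13, and 93.0% of the peaks lay within 3 h of each other. Against 4sU exon RNA the lag was 0.35 h (quartiles 0.0893 to 0.772 h, 172 genes). No gene had a 12-h rhythm in both layers.

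The last comparison asked whether the 4sU/total ratio was itself rhythmic. In shCTRL the ratio of Spon2 had a 24-h amplitude of 0.20 ± 0.0274 with a peak at 30.3 h (limma adjusted p = 0.0332), 1 of 2 genes called (0 without the 28, 30, 34 or 46 h time point and 1 without the 26, 32, 36, 38, 40, 42 or 44 h one). In shBmal1 the largest amplitudes were those of Mttp (1.79 ± 0.293, 25.9 h), Ccl5 (0.89 ± 0.199, 26.8 h), the ribosomal protein gene Rps27 (0.86 ± 0.182, 43.4 h) and Pet117 (0.80 ± 0.132, 42.9 h). Ribosomal protein genes were called in 14 of 26 (16 adjusted over the list alone; Fisher adjusted p = 0.000779) and mRNA decay factors in 15 of 39 (15 adjusted over the list alone; 0.0206). Limma called 1955 genes (18.0% of 10870) in shBmal1 and 10 with a differential rhythm, so for most of these genes the ratio's rhythm was not shown to differ from that in shCTRL. The 1955 calls fell to 0 with a linear term and to 3 when shBmal1 was fitted alone, both by limma, and were 464, 763, 803, 895, 941 and 1257 without the 40, 28, 30, 42, 34 and 46 h time point.

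**Figure D4:**
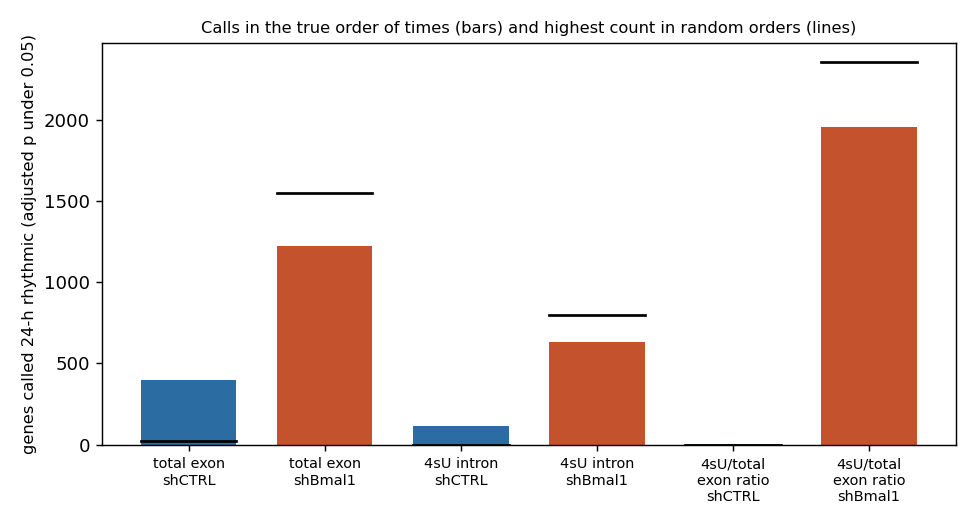
Bars show the number of genes with a 24-h rhythm in total exon, 4sU intron and the 4sU/total ratio in each line, and black lines the highest number in 99 random orders of the time points. The random orders reached 21, 1 and 1 genes in shCTRL, against 396, 116 and 2 in the real order, and 1551, 798 and 2351 in shBmal1, against 1225, 634 and 1955.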

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

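The tests of transcript lengths, of intron totals and, for total exon RNA, of the scatter between cultures were chosen only after the results were seen, and the removal of a 30 h component was chosen after the data were seen but before its own result.

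The 24-h rhythm differed between the lines by a test of the difference itself in 93 genes of total exon RNA and 31 of 4sU intron RNA. In total exon RNA the fitted curves were apart by 1.03 on the log2 scale for Per2, 0.93 for Cry1, 0.98 for Nr1d1, 1.32 for Arntl, 0.58 for Bhlhe40 and 1.36 for Nfil3. With the lines swapped at random within time points, 1 of 100 assignments, the real one, gave as many genes in total exon RNA (highest other 14). In 4sU intron RNA 2 of 100 did, with another assignment giving the same 31 genes. Both shares were under 0.05, with no adjustment for the number of such tests. Swapping the lines breaks up a drift that differs between them as well as a cycle that differs, so the shares do not tell these apart. With a linear term for time fewer genes were called in both layers, as given above. For the 12-h period, where 0 genes were called by limma (508 and 415 at an unadjusted p under 0.05), all 100 assignments gave as many, which a count of 0 fixes in advance and which therefore tests nothing, the highest others being 9 and 1. In total intron RNA, a second measure outside the planned comparisons, limma called 54 genes with a 12-h rhythm in shBmal1 and 2 whose 12-h rhythm differed between the lines. In the 4sU/total ratio limma called 20 genes with an 8-h rhythm in shBmal1, a period no comparison asked for. No random orders or other settings were tried on that layer or that period, so chance is not excluded for these calls. Random orders of shBmal1 gave up to 1880, 502 and 1857 genes with a 12-h rhythm in total exon, 4sU intron and the ratio.

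Other splits and orders of the libraries were drawn for the line means and rhythms. For the line means the real split alone of 100 gave as many genes: 245 against at most 90 in total exon, 93 against 1 in 4sU intron and 66 against 0 in the ratio. Of these calls 63, 44 and 64 were genes with more than 1 length. Lengths follow the groups, so only the real split keeps that offset whole, and for those genes the test decides nothing. For 24-h rhythms of shCTRL the real order alone of 100 gave as many, 396 against at most 21, 116 against 1 and 2 against 1 in the same layers. In shBmal1, 4 orders of 100 gave 1225 or more in total exon (highest other 1551). In 4sU intron 3 gave 634 or more (highest other 798), and in the ratio 2 gave 1955 or more (highest other 2351). Each share was under 0.05, with no adjustment for the number of such tests. A random order breaks up a drift over time as well as a cycle, so the shares do not tell a drift from a cycle. Orders that call as many genes as the real shBmal1 order point to a structure of the shBmal1 samples that many genes share. For the 12-h period 9 orders of 100 gave 2 or more genes in shBmal1 total exon (highest other 1880, many times the real count), so chance is not excluded there. Against a real count of 0 all 100 orders give as many by construction, which tests nothing: the highest others were 40 in shCTRL total exon, 39 and 502 in shCTRL and shBmal1 4sU intron, and 1 and 1857 in the ratio, where limma called 0 genes with 353, 294, 2050, 468 and 511 at an unadjusted p under 0.05.

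In shBmal1 more genes had a 24-h rhythm than in shCTRL in total exon RNA (1225 and 396) and in the ratio (1955 and 2), while clock amplitudes were smaller there. A component that sets the shCTRL 30 h culture apart is argued against as the whole cause of the excess. With it taken out of the shBmal1 libraries 1773 and 1295 genes were called there, still more than in shCTRL under the same setting. The lines share 1 residual spread, and the shCTRL count in total exon rose too, so these counts do not measure the component alone. The ratio's count fell from 1955 to 1295, so a part of the component in it stays open. A linear drift is argued against, though weakly, for the size of the ratio's rhythms, which were 1.23 times as large with a linear term as without (quartiles 1.01 to 1.45). Over 1 period a linear term overlaps with the 24-h terms, which makes the fitted amplitude less certain, and limma then called 0 of them. How amplitudes behave in that model was not simulated. Drift stays open for total exon, where the value was 0.548 with quartiles of 0.349 and 0.795. These lie on both sides of a bound of 0.5 set before, the quartiles being considered only after the median was seen. More scatter between shBmal1 cultures, measured against 1 shared spread, may account for the excess: fitted alone, shBmal1 had 325 genes in total exon and shCTRL 707, and the residual variance of shBmal1 was 1.63 times that of shCTRL in the ratio and 1.79 times in total exon. The lower Bmal1 level of shBmal1, which the design names, also stays open and was not tested apart from these.

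Large differences between the lines were enriched in genes whose RPKM rest on 2 transcript lengths. The lengths may account for this part: 25.7% of the called total exon genes had 2 lengths, against 5.35% of those tested, and 58 of these 63 changed in the direction that the lengths alone give. As the cause of all differences the lengths are argued against by the 181 called genes with 1 length in both lines. For those 181, the hairpin and any other difference between 2 separately derived stable lines stay open and were not tested.

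Deposited 4sU intron RPKM was lower in shBmal1, with a median over genes of 0.490 ± 0.0212 (SD, n = 12) against 0.691 ± 0.0311 in shCTRL, a ratio of 0.710. Normalisation to a larger total in the shBmal1 4sU intron columns may account for it, since on the exon totals the median was 0.673 ± 0.0343 and the ratio 0.974. A change in total RNA synthesis, the biological explanation the design offers, could not be tested, because RPKM are relative and the deposited tables hold no spike-in values.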

How the results depend on the processing

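The alternatives with genes of 1 length, without the shCTRL 30 h culture, with a length trend or a 30 h component removed and with voom weights were chosen only after the data were seen. Line mean counts were within 1.5 times of their values with no filter on low values, with each time point left out (total exon 93 to 100 higher and 138 to 153 lower, 4sU intron 51 to 60 and 33 to 40, ratio 30 to 34 and 31 to 34) and without time terms. The lines' libraries share only time points, which were put in as a replicate block: the counts were then 97 and 148, 55 and 36, and 33 and 33. Deviations of same-time libraries from their line means correlated from -0.18 to 0.41 in total exon, with 9 of 12 pairs over 0.1, and 2 of 12 correlated best with their own time, so no pairing was assumed. The lag of total exon behind 4sU intron was 1.00 to 1.15 h with each time point left out and 0.85 h with a linear trend. For the changes below the cause was not tested, except where fewer genes, fewer samples or a looser threshold are the alternative's own construction.

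With a pseudocount 10 times larger, higher and lower genes were 40 and 85 in total exon, 29 and 18 in 4sU intron, and 19 and 17 in the ratio. Without the size threshold they were 3748 and 3619, 2361 and 2307, and 1765 and 1290. With genes of 1 length only they were 60 and 121, 23 and 19, and 0 and 2. As deposited, the RPKM gave 27 higher and 229 lower in 4sU intron, 154 genes with a 12-h rhythm in total exon of shBmal1, and 1 with a 24-h rhythm of the ratio in shCTRL.

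With a linear trend, 24-h calls of shCTRL and shBmal1 and differential calls were 112, 13 and 30 in total exon and 45, 6 and 10 in 4sU intron, the ratio had 0 and 0, and total exon of shBmal1 had 0 with a 12-h rhythm. At an adjusted p under 0.2 these counts were 1122, 2867 and 388, then 495, 2448 and 281, then 6 and 4732 in the ratio, and 2577 (total exon) and 1280 (4sU intron) genes of shBmal1 had a 12-h rhythm. With separate fits, shCTRL and shBmal1 had 707 and 325 in total exon, 269 and 26 in 4sU intron and 0 and 3 in the ratio, and 12-h rhythms in shBmal1 were 0 in total exon and 1 in the ratio. Without the shCTRL 30 h culture, 12-h rhythms in shBmal1 were 5 in total exon, 1 in 4sU intron and 1 in the ratio, the 4sU intron differential count was 16 and the ratio in shCTRL had 0. With the length trend removed, 12-h rhythms in shBmal1 were 1 in total exon and 1 in 4sU intron, and the 24-h counts of shBmal1 were 1350 and 1966 in total exon and ratio. With the 30 h component removed, 24-h calls of shCTRL were 691 in total exon, 197 in 4sU intron and 1 in the ratio, those of the ratio in shBmal1 1295, and 12-h calls in total exon of shBmal1 4.

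With each time point left out, 24-h counts in total exon ranged from 204 to 467 in shCTRL (204 without 38 h or 40 h, 242 without 42 h, 262 without 44 h) and from 381 to 1828 in shBmal1 (381 without 40 h, 724 without 38 h, 775 without 42 h, 779 without 30 h), and differential counts from 39 to 173 (39 without 38 h or 40 h, 45 without 36 h, 51 without 44 h, 55 without 42 h, 60 without 30 h, 173 without 32 h). In 4sU intron they ranged from 47 (without 38 h) to 207 (without 24 h) in shCTRL, with 49, 61, 61, 63, 70, 75, 77 and 184 without 40, 36, 42, 44, 34, 26, 30 and 46 h. In shBmal1 they ranged from 139 (40 h) to 1545 (32 h), with 238, 304, 310, 339 and 415 without 30, 42, 34, 36 and 38 h. Differential counts there ranged from 8 (44 h) to 245 (32 h), with 10, 11, 12, 13, 14, 20 and 52 without 36, 34, 42, 30, 40, 38 and 26 h. The ratio ranged from 0 (28, 30, 34 and 46 h) through 1 (26, 32, 36, 38, 40, 42 and 44 h) to 2 in shCTRL and from 464 to 2351 in shBmal1, with 464, 763, 803, 895, 941 and 1257 without 40, 28, 30, 42, 34 and 46 h. For the 12-h period, total exon ranged from 0 to 2 in shCTRL (2 without 46 h) and from 0 to 1980 in shBmal1 (1980, 1301, 472 and 167 without 32, 26, 24 and 30 h, 0 without any other), 4sU intron of shBmal1 from 0 to 709 (169 and 709 without 24 and 32 h), and the ratio of shBmal1 from 0 to 1 (1 without 28, 32 or 34 h).

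Of 2950 recomputed values of 464 named gene results, 2496 were the same, 402 lost and 14 gained their call, and 38 turned, 32 of them as deposited. The losses were uneven. With a linear trend, which was applied to rhythms alone, 153 lost their call and 61 were the same. With separate fits, also for rhythms alone, 93 lost it and 97 were the same. At the least favourable left-out time point 99 lost it and 361 were the same. In 4sU intron as deposited Clock was -0.29, Per1 -0.44, Cry2 -0.15, Ciart -0.22 and Csnk1d -0.45, where the larger intron totals of shBmal1 are the cause by construction. Per1 reached -0.00581 in 4sU intron with a time point left out, Nr1d2 -0.00667 in the ratio with the larger pseudocount, and Bhlhe41 in the ratio -0.00738 as deposited, -0.00490 with the larger pseudocount and -0.000980 with a time point left out. Under the replicate block 9 named gene results lost and 1 gained their call; Arntl in 4sU intron kept its log2 fold change of 0.57 with an adjusted p of 0.0533 (8.38e-06 to 0.187 over the alternatives). Depth was at least 48873013 reads per library, and how much of the spread it accounts for was not tested.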

Other observations

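All hypotheses of this part were tested only after the result was seen.

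In shCTRL, newly made RNA relative to RNA present (the 4sU/total exon ratio minus that of all genes, 9775 genes with 1 length) ranked gene groups in a way no comparison between the lines shows. It was highest in the core clock (median 0.45 on the log2 scale, 16 genes) and in immediate early genes (0.38, 19 genes), above 99.96% and 100% of 10000 random lists of like expression. Clock outputs (0.31), p53 targets (0.29) and mRNA decay factors (0.24) came next, above 99.65%, 100% and 99.99% of the random lists. Cholesterol synthesis (-0.08) and inflammatory genes (0.11), with medians nearer to that of all genes, still lay above 99.89% and 99.42%. Extracellular matrix genes (-0.71, 23 genes), actin and SRF targets (-0.64, 11 genes) and NRF2 targets (-0.51, 20 genes) were low, above 3.99%, 0.86% and 2.95%. Ribosomal protein genes (-0.60) and oxidative phosphorylation genes (-0.52) lay at 12.3% and 5.11%, near lists of like expression. The random lists were matched on expression alone, and not on transcript length or uridine content. Whether these shape the recovery of 4sU RNA, and with it the ranking, was not tested. These values describe the 12 shCTRL cultures as a set and test no condition.

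Among single genes, chosen after their values were seen, the ratio was lowest for Ccnb1ip1 (-3.85), Ccdc107 (-2.32), the small nucleolar RNA host Snhg3 (-1.99) and the histone genes H2bc6 (-1.64), H2bc4 (-1.55) and Hist1h2bp (-1.43). It was highest for the growth factor gene Bmp7 (1.60), Cep295nl (1.19), Hic2 (1.06), the homeobox gene Hoxb5 (1.03) and Ppp1r15b (1.03), which encodes a regulator of the translation factor eIF2. In shBmal1 the log2 level of Nfil3 in total exon RNA was 4.42 at 46 h and 3.31 to 3.61 at the other time points.

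Averaged over the course, Arntl exon RNA was lower in shBmal1 while its newly made intron RNA was not. One hypothesis is that the hairpin acts after transcription, as hairpins do by design, which needs an intron signal that is not lower. The log2 fold change of Arntl in 4sU intron was 0.57 ± 0.0810, or 0.11 on the RPKM as deposited, so a loss of transcription averaged over the course is argued against and the hypothesis may hold. At 32, 34, 36 and 38 h, around the shCTRL peak, the intron signal was lower in shBmal1 (log2 level 0.02 against 0.18 at 34 h). For those time points a loss is not argued against. As deposited, all genes shift by a median of -0.46, so that setting does not bear on Arntl. Without time terms the fold was still 0.57 and limma's adjusted p 0.0848 (8.38e-06 to 0.187 over the alternatives), so whether the mean intron signal over the course was higher, and not only not lower, stays open.

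Cell cycle genes were called with a 24-h rhythm in shBmal1. One hypothesis is a decline over the course in place of a cycle. With a linear term in the model limma called 0 of the 20 G2/M genes called in total exon of shBmal1. Over 1 period that term overlaps with the 24-h terms, and core clock calls fell from 7 to 1 with it. The loss of calls therefore does not tell a decline from a cycle. The mean of the G2/M list did fall, with a Spearman correlation with time of -0.97 in shBmal1. The calls may reflect a decline or part of a cycle, and with 1 period sampled a repeat of a cycle could not be looked for. A wave of division after serum that both lines share was also asked about, but its test decides nothing. The median peak of the 24 G2/M genes was 30.0 h in shCTRL and 29.4 h in shBmal1, a difference of 0.65 h, and a straight fall over these time points has a fitted peak at 29.0 h whatever its cause.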
